A study of Mastomys natalensis with 3 samples.

How the data were processed

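RNA of 3 samples of Mastomys gastric cells was hybridised to an Affymetrix rat array, 1 array per sample, per the labels. Groups were taken from the description of each sample, which gives loxtidine for 8 weeks, loxtidine for 16 weeks, or a spontaneous gastric ECL cell carcinoid. The number of animals behind each sample was not given in the sources used here. Because rat probes met Mastomys RNA, sequence differences can dim a probe set. Each probe set was therefore compared only with itself across arrays. This assumes that such differences act on every array alike, which was not tested.

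The deposited table holds 1 intensity per probe set and array, on a linear scale, as made by the authors. The algorithm, background correction and scaling behind it were not given in the sources used here, and no detection calls were used. The 2% trimmed means of the deposited intensity were 18.1, 25.5 and 27.6 for 8 weeks, 16 weeks and carcinoid. They differed by over 5%, and a rule fixed before the data were examined then called for quantile normalization of the 3 arrays. Quantile normalization forces the same distribution on each array and so hides any shift shared by most transcripts.

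Gene symbols came from the platform annotation provided with the data. Of 8740 non-control probe sets, 7006 had 1 symbol, 308 had several and 1426 had none. Only probe sets with 1 symbol were named, covering 4736 genes, of which 3658 reached the floor on at least 1 array. Chga and Ccn2, on the list of genes to be named always, had no singly named probe set in the annotation used and are not analysed here.

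The floor was the pooled median of the normalized non-control values, 12.4. Values below it were raised to it before log2. A fold is given where both arrays were at or above the floor, a bound ("at least") where only 1 was, and no fold where neither was. The deposited unit of intensity does not give a depth. The 4371 to 4379 probe sets per array that reached the floor follow from its definition. With 1 array per group no significance test of a difference between groups was run. Counts of probe sets at least 2-fold and at least 4-fold apart have exact binomial 95% intervals, which cover only the sampling of probe sets. The spread between probe sets used 1 pair of probe sets per gene, and some pairs were made from the same sequence. It was the root mean square of the difference between the pair's log2 differences, divided by the square root of 2. It holds no variation between animals.

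A gene took the value of its probe set with the highest mean deposited intensity. The genes named were chosen by a rule fixed before the data were examined. Per comparison it took the 8 genes with the largest difference each way among those measured on both arrays, the 4 with the largest bound each way, and up to 4 genes per list. It added the 5 furthest above and the 5 furthest below both other arrays for each array, and always Hdc, Chga, Slc18a2, Cckbr, Ccn2 and Gast. Some list members and apart genes that the rule named are not printed. Other probe sets of a named gene are given where they differed in sign or by over 1 on the log2 scale. The gastric genes given among the other observations were chosen from the fixed lists after their values were seen.

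The 24 gene lists were fixed beforehand. They covered neuroendocrine and ECL cell markers, regulated exocytosis, parietal, chief and mucous cells, other gut hormones, epithelial adhesion and keratins, neuron and glia, smooth muscle, extracellular matrix and fibroblast, endothelium, leukocyte and MHC class II, mast cells, erythroid genes, cell cycle, immediate early genes, heat shock and chaperones, growth factors and receptors, apoptosis, glycolysis, ribosomal proteins, the mitochondrial respiratory chain, the proteasome and channel subunits. Each list's median log2 difference over genes above the floor on at least 1 array has an order-statistic 95% interval over genes. Its percentile came from 10000 random lists matched in size and in 10 bins of mean intensity.

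Alternatives fixed beforehand were the intensities as deposited, scaling by the median, the floor at the 25th percentile (4.2) or the 75th percentile (30.0), log2 of the value plus the floor without a filter, 1 probe set per gene for the counts, and the median of all probe sets of a gene. Restricting to EST probe sets was added after the 5' controls had been seen to be dim on the 8-week array. The steps were tested on simulated data with planted differences in 200 of 8799 probe sets. For 16 against 8 weeks, 40.3%, 77.6% and 86.4% of the probe sets planted at 2-fold, 4-fold and 8-fold were called at least 2-fold apart in the planted direction. The same shares were 41.8%, 73.1% and 92.4% for carcinoid against 8 weeks and 46.3%, 86.6% and 86.4% for carcinoid against 16 weeks. Of unchanged probe sets, 25.3%, 31.1% and 18.1% were called apart in those comparisons, with noise set from the deposited differences between arrays at like intensity. The real arrays held fewer, with 10.8% higher and 9.86% lower, 11.8% and 11.3%, and 7.01% and 6.25%. The simulated noise was thus larger than the spread between the normalized arrays at this cutoff. That noise also holds any real difference between the groups, so the shares called apart do not measure error alone. Whether a 2-fold difference of a single probe set exceeds measurement noise could not be told from this simulation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.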

Results

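RNA from the stomach of Mastomys natalensis, an African rodent prone to gastric carcinoids, was measured on 3 Affymetrix rat expression arrays. Per the labels, each array held cells of the gastric mucosa enriched for enterochromaffin-like (ECL) cells, the histamine-storing endocrine cells of the acid-secreting mucosa. Animals of 2 groups had received loxtidine, which blocks the histamine receptor that drives acid secretion, for 8 or 16 weeks. Animals of the third group had developed an ECL cell carcinoid spontaneously. Each group had 1 array, so no difference has a replicate check, a standard error or a p-value, and the values describe these arrays. The source field of the labels named ECL cells for the 8-week sample and gastric mucosa for the other samples.

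Each array reported 8799 probe sets, of which 59 were controls. The median deposited intensity was 10.1 on the 8-week array, 13.1 on the 16-week array and 13.8 on the carcinoid array. After quantile normalization, 4371, 4379 and 4371 non-control probe sets, in that order, lay at or above the floor of 12.4. The floor, a pooled median, fixes these counts by construction, so they do not show how many transcripts each array detected. Of 38 control probe sets taken to have no target in this RNA, 8, 9 and 9 also reached the floor. A value just above it can therefore not be safely told from background. These controls were chosen by name, and a target for some, such as murine controls or added spikes, was not excluded. The number of arrays limits the precision of every value. The only error that could be measured was the spread between probe sets of the same gene. It came to 0.79 on the log2 scale for 16 against 8 weeks (410 genes), 0.84 for carcinoid against 8 weeks (395 genes) and 0.63 for carcinoid against 16 weeks (457 genes). Over all probe sets measured on both arrays, the SD of the log2 differences was little larger, at 0.85, 0.88 and 0.68. In 33.9%, 38.7% and 26.9% of those genes the probe sets compared lay over 1 apart on the log2 scale. A fold from 1 probe set may therefore reflect that probe set more than the gene.

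Control probe sets along the GAPDH and beta-actin transcripts differed most between the 8-week array and the others. The GAPDH 5' probe set read 37.3 on the 8-week array, 364 on the 16-week array and 344 on the carcinoid array (deposited intensity). The corresponding 3' readings were 334, 520 and 793. The ratio of 3' to 5' was therefore 8.95, 1.43 and 2.31 for GAPDH, and it was 16.1, 6.71 and 11.7 for beta-actin. The 9 bacterial hybridisation controls had a median log2 difference of -0.17 (16 against 8 weeks), -0.55 (carcinoid against 8 weeks) and -0.33 (carcinoid against 16 weeks) in the deposited values. After quantile normalization these were -0.82, -1.35 and -0.45. Normalization thus moved these bright controls down on the 16-week and carcinoid arrays relative to the 8-week array. Lower values of bright genes on those arrays may hold part of such a shift. Each array also carried a lot label of its own, so lot and group cannot be told apart.

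**Figure D1:**
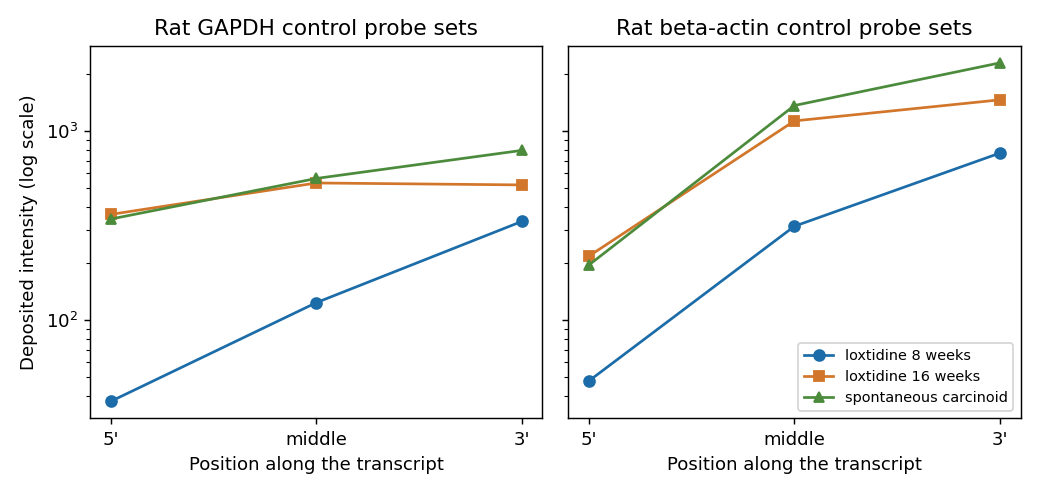
Deposited intensity (log axis) of the rat GAPDH and beta-actin control probe sets by position along the transcript, with 1 line per array. The 8-week array had the lowest 5' reading of GAPDH, 37.3 against 364 and 344.

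Probe sets at least 4-fold above or below both other arrays were counted to see which array stood apart. On the 8-week array 28 probe sets lay above and 47 below both others (11 and 106 as deposited). The 16-week array had 4 above and 5 below, and the carcinoid array 10 above and 9 below. Genes furthest above on the 8-week array included Egr1 (11.8-fold over the nearer array), the apolipoprotein Apoc3 (at least 7.02-fold) and Prp15 (at least 6.66-fold). The Prp15 probe set is of the kind shared by a gene family, so its identity is uncertain. Next came the keratin Krt4 (6.3-fold) and Odc1, the first enzyme of polyamine synthesis (at least 6.15-fold). Furthest below were the gastric mucin Muc5ac (10.6-fold), the lysosomal tetraspanin Cd63 (8.14-fold) and the glycolytic enzyme Aldoa (6.32-fold). The 16-week array held the highest values of the cytokine-signalling inhibitor Socs3 (4.44-fold) and the small heat shock protein Hspb2 (3.97-fold). It held the lowest values of the mitochondrial citrate carrier Slc25a1 (4.62-fold) and of Rbm24 (4.61-fold). The carcinoid array stood above both others for the galectins Lgals4 (at least 6.28-fold) and Lgals3 (at least 4.61-fold), and below both for Abcc9 (6.14-fold) and Gdnf (at least 4.65-fold). Across probe sets measured on both arrays of a pair, log2 intensities correlated least between carcinoid and 8 weeks (r = 0.771, rho = 0.649, 3122 probe sets). The correlation was 0.789 between 16 and 8 weeks (rho = 0.672, 3164 probe sets) and 0.862 between carcinoid and 16 weeks (rho = 0.742, 3311 probe sets). Probe sets are not independent replicates.

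The first comparison set 16 weeks of loxtidine against 8 weeks. Of 21 immediate early genes, which respond within minutes to stimulation or stress, 8 were at least 2-fold lower at 16 weeks and 1 at least 2-fold higher (6 and 3 as deposited). The transcription factor Egr1 was 32.4-fold lower at 16 weeks (intensity 96.4 against 3126), and Jun was 10.6-fold lower (40 against 424). Muc5ac was 10.6-fold higher at 16 weeks (168 against 15.8), and its other probe set was 6.39-fold higher. Cd63 was 8.14-fold higher (113 against 13.9). With the floor at 30.0, these brightest probe sets were at least 5.61-fold and at least 3.76-fold higher. Of the 38 controls taken to have no target, 5, 0 and 3 still reached that floor. The translation initiation helicase Eif4a2 was 8.59-fold higher on 1 probe set and 12.1-fold higher on the other, both made from the same sequence. Of 3164 probe sets measured on both arrays, 343 were at least 2-fold higher at 16 weeks (10.8%, exact 95% interval 9.78 to 11.98%) and 312 at least 2-fold lower (9.86%, 8.84 to 10.95%). At 4-fold the counts were 43 and 39, and a further 52 higher and 40 lower had a bound of at least 4-fold because the other array was below the floor. Higher probe sets made up 52.4% of the 2-fold differences after quantile normalization and 83.2% in the values as deposited, where all probe sets shifted by a median of 0.39. The 8-week array in this comparison is that with the dim 5' controls. It is also the only array whose source field named ECL cells and not gastric mucosa.

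Other genes far lower at 16 weeks included the transcription factor Cebpb (11.01-fold), the NF-kappaB inhibitor Nfkbia (10.2-fold) and the clathrin adaptor subunit Ap2m1 (9.63-fold). Their 16-week values of 12.4, 13.1 and 15.2 lay near the floor, and with the floor at 30.0 they were at least 4.57-fold, 4.43-fold and 4.87-fold lower. Of the 16 largest measured differences of this comparison, 11 had a dimmer value under 30.0, so their sizes and order are uncertain. Apoe, a lipid carrier, was 8.04-fold lower, and its second probe set 5.75-fold lower. The mRNA-decay factor Zfp36 was 7.42-fold lower on its brightest probe set and 1.75-fold lower on the other. Krt4 was 6.3-fold lower. Genes at or above the floor on the 8-week array alone gave bounds. Pancreatic lipase, Pnlip, was at least 10.3-fold lower at 16 weeks, the complement component C1qb at least 7.42-fold, Apoc3 at least 7.02-fold and Mamdc4 at least 6.84-fold. In the other direction the tachykinin precursor Tac1 was at least 7.44-fold higher, Magt1 at least 6.46-fold and Wdr62 at least 6.2-fold. Rnf130 was at least 6.44-fold higher, with a second probe set 2.71-fold higher. Aldoa was 6.32-fold higher and the tRNA-modifying enzyme Dus1l 5.7-fold higher.

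Several of these genes had probe sets that disagreed. The remaining Egr1 probe sets were 8.44-fold lower, 2-fold lower and at least 1.56-fold higher at 16 weeks. A second Jun probe set was 36.6-fold lower, and another at least 1.67-fold lower. The growth factor Igf1 was 9.98-fold higher on its brightest probe set (3724 against 373). Of its other probe sets, 1 pair was at least 3.36-fold and at least 3.46-fold higher, and another was at least 1.59-fold lower. Those other probe sets read 46.2 or less as deposited on every array, against 4249 at 16 weeks for the brightest. The identity of the brightest signal is therefore uncertain. Atp5po, an ATP synthase subunit, was 7.39-fold higher on its brightest probe set and 1.95-fold lower on the other. For the aminopeptidase Aopep, 6.51-fold higher, another probe set was 1.94-fold lower and another at least 2.05-fold higher.

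Gene lists fixed before the data were examined were summarised by the median log2 difference of their genes and by its percentile among 10000 random lists of like size and intensity, a description of these arrays. The immediate early list had a median of -0.86 (95% interval -1.30 to -0.17, percentile 0.0), and -0.42 as deposited, with percentiles of 0.0 to 0.03 over the alternatives with all probe sets. Junb was 5.68-fold lower on 1 probe set and 1.68-fold lower on the other. Of 18 heat shock and chaperone genes, 2 were higher and 4 lower (3 and 1 as deposited), with a median of -0.57 (-1.0 to 0.13, percentile 0.65, up to 7.54 over the alternatives), which was -0.07 as deposited and 0.00 over 11 genes with EST probe sets. The co-chaperone Dnajb1 was 5.81-fold lower, and its second probe set 7.15-fold lower. The mitochondrial chaperonin Hspd1 was 2.7-fold lower on 1 probe set and 1.02-fold lower on the other. As deposited the former read 412 at 16 weeks against 568 at 8 weeks. Of 24 extracellular matrix and fibroblast genes, 1 was higher and 6 lower (2 and 2 as deposited), with a median of -0.42 (-0.85 to 0.00, percentile 0.82). That median was 0.00 as deposited (percentile 5.15) and 0.10 over the 8 genes with probe sets made from expressed sequence tags (ESTs), a choice made after seeing the data. Decorin, Dcn, was 3.45-fold lower and the collagen gene Col5a1 2.74-fold lower. Decorin's other probe sets were 1.61-fold lower, at least 1.82-fold lower and at least 4.11-fold lower.

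Of 43 cytosolic ribosomal protein genes, 6 were at least 2-fold higher at 16 weeks and 2 lower (15 and 1 as deposited). Their median was 0.32 (0.00 to 0.42, percentile 98.9), and 0.07 (percentile 70.3) over 20 genes with EST probe sets. Rps9 was 3.5-fold higher and Rpl7a 2.49-fold higher, whereas Rpl17 was at least 5.83-fold lower. Proteasome genes, 6 higher and 1 lower of 25, had a median of 0.33 (0.06 to 0.82, percentile 95.2), and 0.09 over 9 genes with EST probe sets. As deposited the proteasome median was 0.81, with 9 higher and 0 lower. Epithelial adhesion and keratin genes, 2 higher and 1 lower of 9 (4 and 0 as deposited), had a median of 0.54 (0.18 to 1.35, percentile 90.5), which was 0.90 as deposited. Keratin 8, Krt8, was 2.84-fold higher, and the junction protein Tjp1 1.81-fold higher. Endothelial genes, 1 higher and 3 lower of 8, had a median of -0.70 (percentile 6.08), and leukocyte and MHC class II genes, 1 higher and 5 lower of 21 (1 and 1 as deposited), -0.30 (percentile 3.17), or 0.00 as deposited. The adhesion receptor Selp was at least 4.84-fold lower at 16 weeks.

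Neuroendocrine and ECL cell markers showed no common direction, with 0 higher and 1 lower of 14 and a median of 0.10 (-0.77 to 0.82, percentile 70.5). As deposited, 3 were higher and 1 lower, with a median of 0.50 (percentile 80.9). The vesicular monoamine transporter Slc18a2 was 1.94-fold higher at 16 weeks, and the gastrin receptor Cckbr was 1.31-fold lower on 1 probe set and at least 2.69-fold higher on the other. Histidine decarboxylase, Hdc, which makes histamine, was below the floor on all 3 arrays (deposited 3.7, 5.2 and 3.4). Gast, the gastrin gene, was at least 2.6-fold lower at 16 weeks than at 8 weeks. Medians of the other cell-type lists were 0.09 for parietal cells, 0.03 for chief cells, -0.13 for mucous cells, -0.26 for other gut hormones, 0.00 for neuron and glia (down to -0.77 over the alternatives), 0.42 for smooth muscle, -0.10 for mast cells and -0.17 for erythroid genes. The means of the parietal, chief and mucous lists had the opposite sign, at -0.09, -0.08 and 0.19. Remaining lists had medians of -0.02 (regulated exocytosis), 0.00 (cell cycle), 0.00 (growth factors and receptors), -0.42 (apoptosis), -0.12 (glycolysis), 0.01 (mitochondrial respiratory chain) and 0.00 (channel subunits). Their percentiles, and those of the cell-type lists just named, lay outside the lowest and highest 2.5%, although smooth muscle reached 98.9 over the alternatives, and neuron and glia 0.68 over 5 genes with EST probe sets (median -0.39). With the values as deposited, the mucous, gut hormone, mast cell, erythroid, exocytosis, apoptosis and glycolysis medians were above 0, at 0.38, 0.23, 0.07, 0.37, 0.14, 0.03 and 0.40, and the gut hormone median was 0.01 with scaling by the median.

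**Figure D2:**
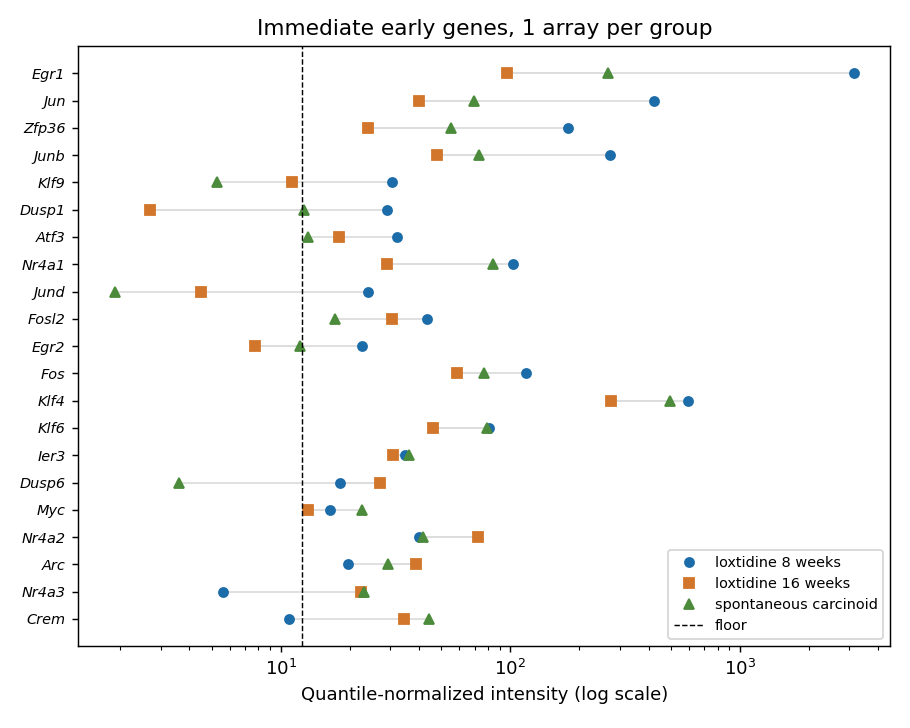
Quantile-normalized intensity (log axis) of immediate early genes, 1 probe set per gene and 1 symbol per array, with the floor of 12.4 as a dashed line. Egr1 read 3126 on the 8-week array, 96.4 on the 16-week array and 265 on the carcinoid array, and Crem was highest on the carcinoid array.

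The second comparison set the spontaneous carcinoid against 8 weeks of loxtidine. The 9 members of the epithelial adhesion and keratin list were all higher on the carcinoid array, 4 of them at least 2-fold, and the ribosomal protein list had a median above 0. The proteasome median was above 0 and the immediate early, heat shock and endothelial medians below it, each with an interval that reached 0, and the heat shock median was 0.08 as deposited. Muc5ac was 13.4-fold higher (213 against 15.8), and its other probe set 4.65-fold higher. Cd63 was 10.2-fold higher (141 against 13.9), and the membrane protein Itm2b 8.35-fold higher (124 against 14.8). Egr1 was 11.8-fold lower (265 against 3126), and the transcription factor Mef2d 8.01-fold lower (15.7 against 126). Of 3122 probe sets measured on both arrays, 368 were at least 2-fold higher on the carcinoid array (11.8%, exact 95% interval 10.7 to 13.0%) and 354 at least 2-fold lower (11.3%, 10.3 to 12.5%). The 4-fold counts were 52 and 39, with bounds of at least 4-fold for a further 59 higher and 45 lower. Higher probe sets made up 51.0% of the 2-fold differences, and 87.5% in the values as deposited, where the median shift was 0.45. The 8-week array, with the dim 5' controls and a source field of its own, entered here too.

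The lipid flippase Atp9a was 7.71-fold higher on the carcinoid array, and its second probe set at least 6.28-fold higher. Aldoa was 7.53-fold higher and the transcriptional corepressor Atn1 6.58-fold higher. Of the 16 largest measured differences of this comparison, 14 had a dimmer value under 30.0. With the floor there, Muc5ac was at least 7.08-fold, Cd63 at least 4.7-fold and Atn1 at least 3.19-fold higher. The kinase Stk39 was 6.93-fold higher on its brightest probe set, 1.71-fold higher on another and at least 3.17-fold lower on the last. The ubiquitin-conjugating enzyme Cdc34 was 6.63-fold higher on 1 probe set, with 1.18-fold higher and 1.05-fold lower on the others. Genes lower on the carcinoid array included Krt4 (6.34-fold), the potassium channel regulator Abcc9 (6.14-fold) and Urgcp (6.07-fold). Another Abcc9 probe set was at least 1.86-fold lower. Jun was 6.12-fold lower, and further probe sets were 38.8-fold and 1.25-fold lower. Or1f32, 10.2-fold lower, came from a probe set shared by a family of olfactory receptors, so its identity is uncertain. The other Egr1 probe sets were 7.52-fold lower, 1.18-fold lower and at least 3.05-fold higher.

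Bounds ran both ways. The clathrin light chain Cltb was at least 9.27-fold higher on the carcinoid array, although another probe set was at least 1.64-fold lower. Rbfox2 was at least 6.6-fold higher and the transporter Slc44a4 at least 6.49-fold higher. Prl8a3 was at least 7.79-fold higher, with other probe sets at least 1.9-fold higher and at least 1.23-fold lower. The natriuretic peptide precursor Nppa was at least 7.73-fold lower and at least 2.93-fold lower on another probe set. The glutathione transferase Gstm7 was at least 6.68-fold lower. The family probe set of the salivary proline-rich protein Prp15 was at least 6.66-fold lower. Apoc3 was at least 7.02-fold lower on its brightest probe set, but at least 2.87-fold and at least 3.34-fold higher on the others.

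Among ribosomal protein genes, 12 of 43 were at least 2-fold higher on the carcinoid array and 2 lower (26 and 0 as deposited), with a median of 0.59 (0.10 to 0.82, percentile 100). Over 20 genes with EST probe sets the median was 0.27 (percentile 88.0). Rpl7a was 3.52-fold and Rpl19 2.93-fold higher, while Rpl23 was 3.22-fold higher on 1 probe set and 1.04-fold lower on the other. Proteasome genes, 7 higher and 2 lower of 25 (13 and 1 as deposited), had a median of 0.47 (-0.10 to 0.88, percentile 99.0), and 0.21 over 9 genes with EST probe sets. The subunit Psmd11 was 3.58-fold higher, and the immunoproteasome subunit Psmb8 at least 3.85-fold lower. The epithelial adhesion and keratin list had a median of 0.91 (0.24 to 1.93, percentile 98.3), which was 1.63 as deposited. Krt8 was 4.89-fold higher, the laminin receptor subunit Itgb4 2.95-fold and Tjp1 2.12-fold.

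Immediate early genes had 1 member higher and 8 lower of 21 (2 and 4 as deposited), a median of -0.61 (-1.30 to 0.05, and -0.29 as deposited) and percentile 1.12, which ran from 0.02 to 6.33 over the alternatives with all probe sets. Junb was 3.73-fold lower and its other probe set 1.82-fold lower, whereas the cAMP-response factor Crem was at least 3.58-fold higher on its brightest probe set. Its other probe sets were at least 1.44-fold higher, 1.55-fold lower and at least 1.03-fold lower. Heat shock and chaperone genes, 0 higher and 5 lower of 18 (2 and 1 as deposited), had a median of -0.54 (-1.08 to 0.00, percentile 1.29, up to 30.8 over the alternatives), which was -0.04 over 11 genes with EST probe sets. Dnajb1 was 6.46-fold lower and 3.44-fold lower on its 2 probe sets, and the endoplasmic reticulum chaperone Hspa5 2.25-fold lower. As deposited Hspa5 read 181.3 on the carcinoid array against 222.5 at 8 weeks. Endothelial genes, 0 higher and 4 lower of 8 (0 and 2 as deposited), had a median of -1.06 (-1.78 to 0.00, percentile 0.52), which was -0.55 as deposited. Over the alternatives it reached -0.33, at percentile 12.5. The growth factor receptor Flt1 was at least 3.43-fold lower and Selp 2.42-fold lower. Other gut hormone genes, 1 higher and 1 lower of 10, had a median of -0.59 (-1.0 to 0.02, percentile 1.77), which was -0.03 (percentile 6.64) as deposited, with percentiles up to 22.1 over the alternatives. Gast was at least 2.6-fold lower on the carcinoid array, a bound that depends on the floor, since its 8-week value was 32.2.

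Extracellular matrix genes, 2 higher and 5 lower of 24 (4 and 1 as deposited), had a median of -0.34 (percentile 3.12), which was 0.13 as deposited. Decorin was 4.16-fold lower, with other probe sets at least 1.61-fold lower, 1.12-fold lower and 1.24-fold higher. Leukocyte and MHC class II genes, 0 higher and 6 lower of 21 (1 and 2 as deposited), had a median of -0.33 (percentile 3.03), or 0.00 as deposited. Neuroendocrine and ECL markers, 0 higher and 5 lower of 14 (1 and 2 as deposited), had a median of -0.41 (-1.10 to 0.13, percentile 7.65), which was -0.16 (percentile 1.44) as deposited. The secretory granule peptide precursor Vgf was 3.09-fold lower, the vesicle protein Syp 2.14-fold and chromogranin B, Chgb, 2.12-fold. Their carcinoid values of 14.2, 26.7 and 17.7 lay under 30.0, so these sizes are uncertain. Cckbr was 2.11-fold lower (40.2 against 54.7 as deposited) and Slc18a2 1.07-fold higher. Medians of the other cell-type lists were -0.10 for parietal cells, -0.02 for chief cells, 0.11 for mucous cells, 0.00 for neuron and glia, 0.64 for smooth muscle (percentile 94.7, up to 99.7 over the alternatives), -0.30 for mast cells and -0.32 for erythroid genes. Remaining medians were 0.00 (regulated exocytosis), 0.00 (cell cycle), 0.00 (growth factors and receptors), -0.58 (apoptosis, percentile 2.6), -0.08 (glycolysis), -0.18 (mitochondrial respiratory chain) and 0.00 (channel subunits). The apoptosis median was -0.08 at percentile 1.51 as deposited, with percentiles up to 36.0 over the alternatives. Growth factors and receptors had 4 members higher and 8 lower of 32 (7 and 6 as deposited), with a mean of -0.20. Their percentile was 48.0, and 1.76 as deposited. The parietal and glycolysis means had the opposite sign, at 0.01 and 0.06. As deposited, the parietal, chief, erythroid, glycolysis and mitochondrial medians were above 0, at 0.66, 0.26, 0.33, 0.61 and 0.33, and the glycolysis median was 0.13 with scaling by the median. The mitochondrial list lay at percentile 11.96, at 2.15 as deposited (14 higher and 1 lower), at 0.49 to 9.83 over all the alternatives fixed beforehand and at 0.35 over 39 genes with EST probe sets (median -0.33).

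**Figure D3:**
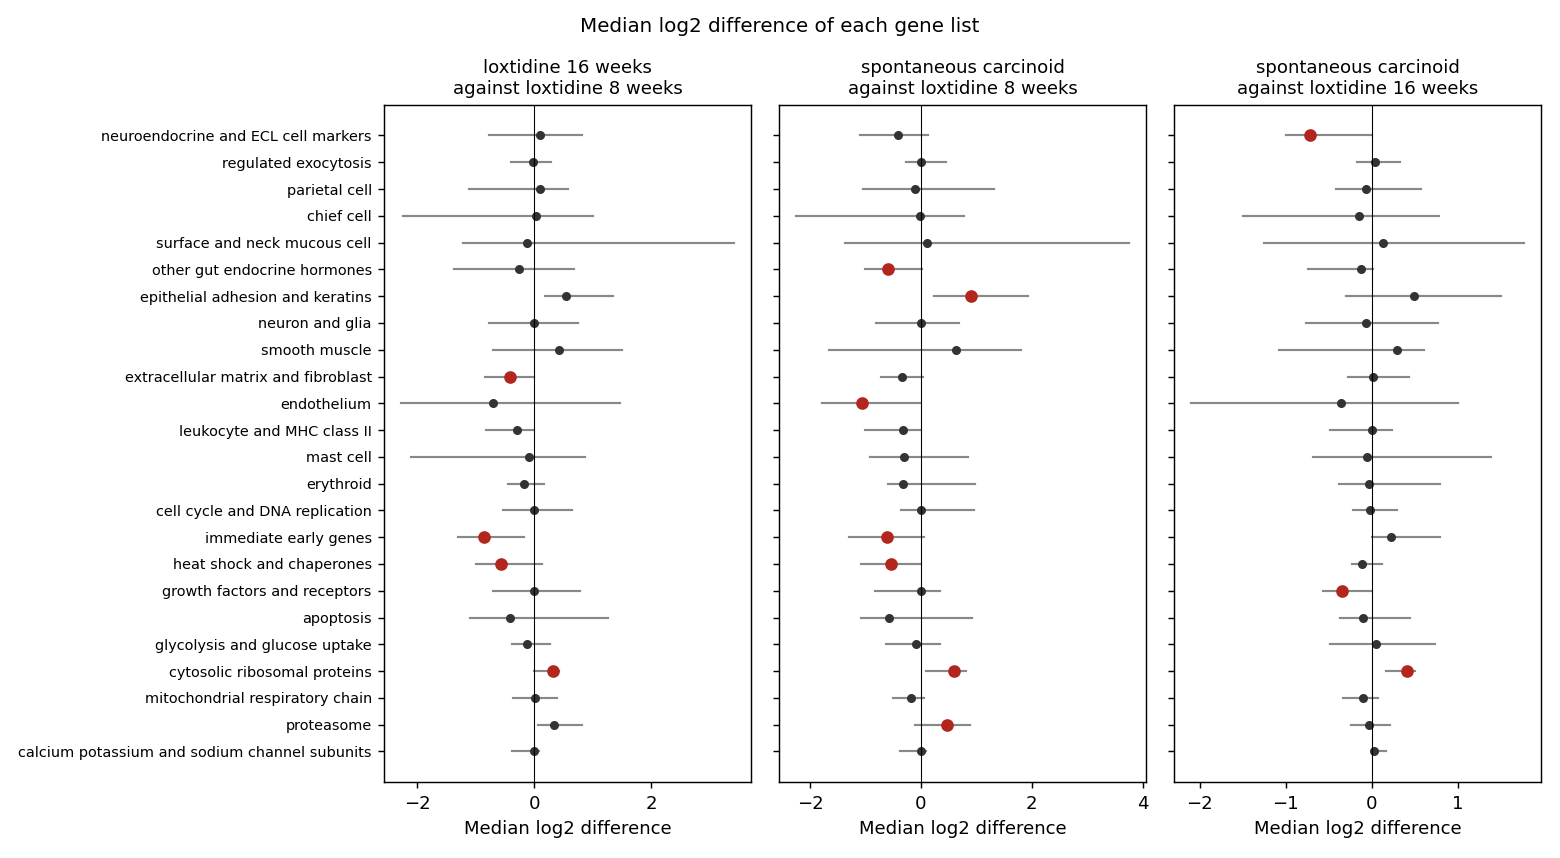
Median log2 difference of each gene list in the 3 comparisons (dots), with 95% order-statistic intervals over the list's genes (grey bars, the whole range for the 4 erythroid genes). Red dots mark medians within the lowest or highest 2.5% of random lists, among them the ribosomal protein list in each comparison, at 0.32, 0.59 and 0.41.

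The third comparison set the spontaneous carcinoid against 16 weeks of loxtidine, the only pair without the 8-week array. Of 14 neuroendocrine and ECL cell markers, 11 were lower on the carcinoid array at any size and 2 at least 2-fold. Of 43 ribosomal protein genes, 31 were higher at any size and 5 at least 2-fold (10 as deposited). Vgf was 3.02-fold lower (14.2 against 42.8), and Chgb just under 2-fold lower (17.7 against 35.4). Both carcinoid values lay under 30.0 and near the floor, so these sizes are uncertain. Lgals4, a galectin of the gut epithelium, was at least 6.28-fold higher (77.9 against 5.2). Of 3311 probe sets measured on both arrays, 232 were at least 2-fold higher on the carcinoid array (7.01%, exact 95% interval 6.16 to 7.93%) and 207 at least 2-fold lower (6.25%, 5.45 to 7.13%). At 4-fold 9 were higher and 12 lower, with bounds for a further 12 and 18. Higher probe sets made up 52.8% of the 2-fold differences.

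Atn1 was 7.35-fold higher on the carcinoid array (95.6 against 13), Cltb 5.93-fold, Slc44a4 5.48-fold and the stress-activated kinase Mapkapk2 4.87-fold. All 16 of the largest measured differences of this comparison had a dimmer value under 30.0, and with the floor there their lower bounds ran from 1.66-fold to 4.05-fold. Slc25a1 was 4.62-fold higher and the endosomal sorting protein Hgs 4.43-fold. Rbm24 was 4.67-fold higher, and at least 1.71-fold higher on its other probe set. The translation factor subunit Eif2b3 was 3.93-fold higher on 1 probe set and 1.15-fold lower on another. Abcc9 was 6.93-fold lower (14.2 against 98.2), and another probe set at least 1.25-fold lower. C2cd4b was 6.31-fold lower, the secreted chaperone clusterin, Clu, 5.05-fold, Socs3 4.77-fold and Mef2d 4.63-fold. The family probe set of Or1f32 was 4.31-fold lower, the ATP synthase subunit Atp5pd 4.07-fold and the small heat shock protein Hspb2 3.97-fold. Bounds placed the mitochondrial enzyme Echs1 at least 4.97-fold, Lgals3 at least 4.61-fold and the anion transporter Slco1a4 at least 4.27-fold higher. Psmb8 was at least 4.94-fold lower, the sperm protease Acr at least 4.72-fold, Lenep at least 4.67-fold and the neurotrophic factor Gdnf at least 4.65-fold.

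Of the neuroendocrine and ECL cell markers, 1 was at least 2-fold higher on the carcinoid array. Their median was -0.72 (-1.0 to 0.00, percentile 0.06), and over the alternatives with all probe sets it ran from -0.71 to -0.37. Cckbr was 1.6-fold lower and at least 2.69-fold lower on its other probe set. Slc18a2 was 1.82-fold lower. Uchl1 was at least 2.16-fold higher. Scg5 was at least 2.71-fold lower on its brightest probe set and at least 2.09-fold higher on the other. Ribosomal protein genes, 2 of them at least 2-fold lower, had a median of 0.41 (0.17 to 0.50, percentile 100), and 0.47 over 20 genes with EST probe sets. Rps24 was 2.46-fold higher, whereas Rps9 was 2.42-fold lower. Growth factors and receptors, 1 higher and 4 lower of 32, had a median of -0.34 (-0.57 to 0.00, percentile 0.88), with a range of -0.41 to -0.01 and percentiles up to 13.6 over the same alternatives. Igf1 was 3.42-fold lower on its brightest probe set, whose identity is uncertain. A pair of its probe sets made from 1 sequence was at least 3.36-fold and at least 3.46-fold lower. That pair was at or above the floor on the 16-week array alone.

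Immediate early genes, 3 higher and 1 lower of 21, had a median of 0.22 (0.00 to 0.79, percentile 91.1). The percentile ran from 49.2 to 99.5 over the alternatives with all probe sets. Over 6 genes with EST probe sets the median was 0.68 (percentile 99.9). Nr4a1 was 2.89-fold higher on the carcinoid array, and its other probe set 2.09-fold. Egr1 was 2.75-fold higher, and its other probe sets were also higher, by at least 1.12-fold. Epithelial adhesion and keratin genes, 3 higher and 1 lower of 9, had a median of 0.49 (-0.30 to 1.5, percentile 94.7). Itgb4 was 2.36-fold higher and Cldn7, a tight junction protein, 2.35-fold lower. Tff2, a trefoil peptide of mucous neck cells, was 3.41-fold higher, and Tff3 2.38-fold lower. The medians of cell-type lists were -0.06 for parietal cells, -0.15 for chief cells, 0.13 for mucous cells, -0.12 for other gut hormones, -0.06 for neuron and glia, 0.30 for smooth muscle, 0.01 for extracellular matrix, -0.36 for endothelium, 0.00 for leukocyte and MHC class II, -0.05 for mast cells and -0.03 for erythroid genes. Remaining medians were 0.04 (regulated exocytosis), -0.02 (cell cycle), -0.11 (heat shock and chaperones), -0.10 (apoptosis), 0.05 (glycolysis), -0.10 (mitochondrial respiratory chain), -0.03 (proteasome) and 0.03 (channel subunits). The mitochondrial list had 2 members higher and 8 lower of 54 (2 and 7 as deposited), with a mean of -0.25 and percentile 13.6. Over 39 genes with EST probe sets its median was -0.13 (percentile 2.41). Parietal, mast cell, erythroid and cell cycle means had the opposite sign to their medians, at 0.10, 0.08, 0.09 and 0.02. As deposited, the parietal, mast cell, erythroid, proteasome and mitochondrial medians were above 0, at 0.13, 0.03, 0.08, 0.13 and 0.01, and scaling by the median gave 0.03 for the parietal and 0.05 for the proteasome list.

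Over all 3 comparisons, 9 of 72 list medians fell in the lowest 2.5% of random lists and 5 in the highest 2.5%. Random lists would put 2.5% of medians in each tail on average. Lists share arrays and genes of like function, so how far such counts vary by chance is not known.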

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

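Alternatives with EST probe sets alone were chosen after seeing the data; the others were fixed beforehand. Values run in the order 16 against 8 weeks, carcinoid against 8 weeks, carcinoid against 16 weeks unless stated, and the cause of a shift was not tested unless given. No named gene at least 2-fold apart changed direction, nor did any list median whose interval excluded 0. Other list medians changed sign in 19 of 72 cases as deposited, 4 of 72 with scaling by the median and 6 of 33 over EST probe sets. With the median of all probe sets of a gene 5 of 72 did so. With the floor at the 25th percentile it was 2 of 72, at the 75th percentile 2 of 69, and with the added floor 0 of 72. Scaling by the median kept all 18 counts within 1.5 times. What the arrays can show is limited by signal over background. Of 38 control probe sets taken to have no target, 8, 9 and 9 reached the floor of 12.4, and 5, 0 and 3 reached 30.0 (8 weeks, 16 weeks and carcinoid). No paired analysis was possible because each group had 1 array.

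As deposited, at least 2-fold higher probe sets numbered 595 and 769 in the comparisons with 8 weeks, and lower ones 120 and 110. At 4-fold, 85, 151 and 19 were higher, and 17 and 14 lower in the comparisons with 8 weeks. The arrays' unequal levels, which this setting leaves in, move these counts by construction. With the floor at the 25th percentile, which admits dimmer probe sets, 1013, 1023 and 793 were at least 2-fold higher and 944, 1012 and 780 lower. At 4-fold these were 271, 301 and 171 higher and 275, 281 and 190 lower. With the floor at the 75th percentile, which leaves fewer probe sets, 120, 140 and 44 were at least 2-fold higher and 104, 121 and 48 lower, and at 4-fold 14, 14 and 1 higher and 6, 9 and 0 lower. Log2 of the value plus the floor, with no filter, gave 701, 787 and 458 higher and 713, 725 and 460 lower at 2-fold, and 5 and 5 at 4-fold for carcinoid against 16 weeks. Over EST probe sets for 16 against 8 weeks, 9.73% were at least 2-fold and 0.94% at least 4-fold higher.

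Probe sets at least 4-fold above both other arrays numbered 11 as deposited, 246 at the low floor, 9 at the high floor and 13 with the added floor on the 8-week array, and those below both 106, 240, 10 and 15. On the 16-week array the same settings gave 9, 120, 0 and 0 above and 1, 118, 0 and 0 below, and on the carcinoid array 25, 154, 0 and 3 above and 5, 140, 0 and 0 below. The spread between probe sets was 0.73 as deposited for 16 against 8 weeks, and 0.73, 0.76 and 0.48 at the high floor.

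List medians moved mostly with the values as deposited. Ribosomal protein genes had medians of 0.84, 1.38 and 0.63 as deposited and 0.45, 0.87 and 0.56 with scaling by the median. For 16 against 8 weeks, deposited medians were 0.37 for erythroid genes, 0.40 for glycolysis, 0.52 for the mitochondrial chain and 0.10 for channel subunits. For carcinoid against 8 weeks they were 0.13 for extracellular matrix, 0.08 for heat shock, 0.61 for glycolysis, 0.33 for the mitochondrial chain, 1.01 for the proteasome and 0.16 for channel subunits. At the high floor the epithelial median for 16 against 8 weeks was 0.08. Over EST probe sets, medians for 16 against 8 weeks were 0.10 for extracellular matrix, -1.75 for immediate early genes and 0.22 for channel subunits, and the last was 0.43 for carcinoid against 8 weeks. Of 351 named values, 16 moved as deposited, 75 at the low floor, 188 at the high floor, 11 with the added floor and 0 with scaling by the median.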

Other observations

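Some genes of acid- and enzyme-secreting cells were well above the floor on every array, although the labels describe enriched ECL cells. Pepsinogen C, Pgc, read 3701, 5703 and 3718 (deposited intensity at 8 weeks, 16 weeks and carcinoid), and the chitinase Chia of chief cells 3032, 7400 and 4324. The proton pump subunit Atp4a read 555, 1566 and 1218 on its brightest probe set, whereas another read 3.5, 102 and 64.6. Intrinsic factor, Cblif, read 311, 534 and 490. Other members of these lists lay below the floor on at least 1 array, such as ezrin, Ezr (3.6, 29.4 and 34.8), the potassium channel Kcnj15 (7.5, 8.9 and 46.0) and gastric lipase, Lipf (2.7, 4.8 and 23.6 on 1 probe set, 16.1, 5.4 and 2.8 on the other). Hdc, the histamine-forming enzyme of ECL cells, read 3.7, 5.2 and 3.4, below the floor on every array. Levels of different probe sets cannot be set against each other, so these values give no share of cell types.

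Of the tests below, those of immediate early genes and of neuroendocrine markers were chosen after their results were seen, and the share of coding-sequence probe sets was added once the mean difference of such probe sets had come out near 0.

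The 8-week array stood furthest apart, and it had the dimmest 5' controls, which may reflect RNA shortened toward the 3' end. In that case probe sets made from coding sequence should be dimmer on it than probe sets made from ESTs, but the mean difference, matched on intensity, was 0.01 (-0.08 to 0.11, 448 coding-sequence and 2452 EST probe sets), which neither shows nor excludes a small effect. The same difference between carcinoid and 16 weeks was -0.04 (-0.11 to 0.03). Coding-sequence probe sets made up 17.0% of those at least 4-fold below both others on the 8-week array (8 of 47, 7.6 to 30.8%) against 7.5% of eligible probe sets, an excess that only just clears its interval and came from the later of the tests. Treatment time, lot and preparation, 1 of each per array, stay open and untested. The source field named ECL cells for the 8-week sample alone and gastric mucosa for the others. A difference in starting material therefore stays open too.

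The immediate early list had a median of 0.86 for 8 weeks minus the mean of the others (-0.02 to 1.21, 15 of 21 genes above 0). Scaling stays open, with a deposited median of 0.41 (-0.43 to 0.83). Shortened RNA stays open too, because the list's 33 probe sets not made from ESTs, with a median of 0.69 (0.06 to 0.92) against 0.62 (-0.2 to 3.01) for its 7 EST probe sets, repeat genes and their positions are not known. Stress during cell isolation, which induces such genes, is a candidate explanation, as is the shorter treatment; neither was tested, with 1 preparation per group. The probe sets of Egr1 disagreed in size and direction, so its 32.4-fold value should not be read alone.

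The neuroendocrine list had a lower median on the carcinoid array than at 16 weeks, at percentile 0.06 of random lists. That percentile picked the list out of 72 medians, so a chance draw of dim probe sets stays open. A smaller share of endocrine cells could lower them and raise every other cell type. Of 11 lists of other cell types, 3 had a median above 0, with medians from -0.36 to 0.30 and 0 lists wholly below 0. The 11 include other gut hormones (-0.12), which also come from endocrine cells, and leave out epithelial adhesion and keratin genes (0.49). The count is therefore a loose measure, and a smaller share of endocrine cells stays open. A lower marker level per tumour cell also stays open and was not tested.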
